A study of Mus musculus with 15 samples.

How the data were processed

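The samples were 15 libraries of RNA from B16.F10 mouse melanoma cells in 1% oxygen, in 5 groups of 3. According to the submitters' notes, RNA was extracted with RNeasy kits and libraries were made with a TruSeq Stranded mRNA kit. The same notes name FastQC 0.11.7, Trimmomatic 0.38, HISAT2 2.1.0, Bowtie2 2.3.4.1 and StringTie 2.1.3b, with the mm10 build. The values are raw read counts per gene, made and deposited by the authors with these tools, and no normalization had been applied to them. The reads themselves were not used here.

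Each group's table lists its own set of genes: 13172 for Control, 12819 for NC_siRNA, 12894 for Hif1a_siRNA, 13080 for Dox and 13073 for Hif1a_siRNA_Dox. The lists of the other 4 groups are subsets of the Control list, and every gene listed for such a group has at least 10 reads in at least 3 of the 6 libraries of Control and that group. The 12721 genes listed for all 5 groups were tested together, and the 451 genes missing from at least 1 group were left out of that fit. Between 24 and 28 gene IDs per table outside Control appear again with identical values and were kept once. Symbols missing from the tables were taken by gene ID from the RefSeq annotation of GRCm38 for 1564 genes; 29 have no symbol. Of the listed IDs 11326 are protein-coding and 1005 are pseudogenes.

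The 15 libraries hold between 23825110 and 28734303 counted reads, and counting error weighs more the fewer reads a gene has. The common biological coefficient of variation was 0.091. A fit with edgeR 4.0.16 in R 4.3.3 used TMM scaling, a group term without a replicate block, robust quasi-likelihood dispersions and two-sided quasi-likelihood F tests on 10 residual degrees of freedom. Its low-count filter (at least 10 reads and a total of 15) removed 0 genes. Adjusted p-values are Benjamini-Hochberg values over the 12721 genes within a comparison, with a threshold of 0.05. The 7 comparisons were Hif1a_siRNA against NC_siRNA, Dox against Control, Hif1a_siRNA_Dox against Dox, Hif1a_siRNA_Dox against Hif1a_siRNA, NC_siRNA against Control, Hif1a_siRNA_Dox against Control, and the difference between the second and the fourth of these.

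Gene lists were tested with camera of limma 3.58.1 on edgeR log2 CPM (prior count 2) with a preset correlation of 0.01, Benjamini-Hochberg over lists within a comparison. There were 27 lists of pathways, complexes and cell type markers, of which 25 had the minimum of 5 tested members. Some genes sit in more than 1 list, such as Egln1 and Egln3 in the HIF regulators and the HIF targets outside glycolysis. Camera was repeated with a correlation estimated from the data and beside fry, which asks whether a list's genes move without comparing them with other genes. The comparisons, tests, lists, the rule for named genes and the alternatives, except where said, were fixed before the data were examined.

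Named genes followed a rule. Hif1a was named in every comparison, with the 6 largest increases and 6 largest decreases among called genes with a mean of at least 5 CPM in the higher group and no overlap between the groups, leaving out clone and prediction names. For the difference of the doxorubicin effects it was the 5 largest in each direction. Genes given as the largest increases, decreases or differences are the largest by this rule, not among all tested genes. The lists described were the HIF lists, the p53 targets and the 3 lists with the smallest camera p in each direction, with the 4 members of smallest adjusted p in each, from which the text takes examples. Members named as exceptions where a count was small, and genes named as examples outside their list's 4, were chosen after their values were seen. Some genes that this rule would name, or that stand among the members or exceptions of a list, are not reported here; they remain in every fit, list and count.

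Alternatives were size factors (RLE), upper-quartile factors, DESeq2 1.42.0, limma-voom, an adjusted p under 0.01, no filter, a filter of 1 CPM in 3 libraries, a replicate block, a fit of only the compared groups, and leaving out each library in turn. Fits of genes listed in both groups and of protein-coding nuclear genes only were added after seeing the data. The closing section gives their effect. The procedure was tested on simulated data with 200 changed genes of 12721. For changes of 1.5-fold, 2-fold and 4-fold it recovered 74.6%, 95.5% and 100% in the knockdown, 80.6%, 95.5% and 100% with doxorubicin, and 64.2%, 88.1% and 100% in the knockdown under doxorubicin. The shares were 74.6%, 95.5% and 100% for doxorubicin after knockdown, 73.1%, 89.6% and 100% for transfection, 67.2%, 91.0% and 100% for the combination, and 52.2%, 74.6% and 100% for the difference. Unchanged genes made up 2.9% to 6.6% of calls. In the real comparisons of group pairs 42.2% to 84.7% of genes were called, so these shares hold for a setting with far fewer changes. Every simulated comparison used the same gene means and dispersions, so differences between those of group pairs may come from the genes drawn. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for tables and plots.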

Results

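Gene expression was measured by RNA-seq in B16.F10 cells, a mouse melanoma line, kept in 1% oxygen. The 15 libraries fall into 5 groups of 3: untreated cells (Control), cells given a negative control siRNA (NC_siRNA), cells given an siRNA against Hif1a (Hif1a_siRNA), cells given doxorubicin (Dox), and cells given the Hif1a siRNA and then doxorubicin (Hif1a_siRNA_Dox). The siRNAs were delivered as lipoplexes at 25 nM, and 24 h is the time recorded between siRNA and doxorubicin. Doxorubicin, an anthracycline that intercalates in DNA and traps topoisomerase II, was given at 0.25 µM for 24 h. The time from siRNA to harvest is not given here for the groups without the drug. Time since transfection may therefore differ between Hif1a_siRNA_Dox and Hif1a_siRNA, and so enter the difference of the doxorubicin effects. Hif1a encodes the oxygen-regulated subunit of the transcription factor HIF-1, which pairs with the product of Arnt. Library totals ran from 25898384 to 26434083 reads in Control, 26345967 to 27394448 in NC_siRNA, 27433068 to 27926937 in Hif1a_siRNA, 24840652 to 25392403 in Dox and 23825110 to 28734303 in Hif1a_siRNA_Dox. The labels call the 3 libraries of a group biological replicates without saying whether they came from separate cultures, so p-values measure the spread between these samples, and nothing here shows whether that spread is biological. No 2 libraries of a group agreed within sampling noise: the chi-square per degree of freedom over genes was 3.56 to 34.49. Levels are given as CPM, a gene's reads scaled to the TMM-corrected library total, as mean ± SD with n = 3, and coordinates are those of the mm10 build.

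The 5 groups separated on the first 2 principal components, which held 73.0% and 14.5% of the variance. The shares of reads in several gene classes also differed between groups. Mitochondrially encoded genes took 1.43% of reads in Control, 1.88% in NC_siRNA, 1.91% in Hif1a_siRNA, 3.77% in Dox and 4.62% in Hif1a_siRNA_Dox. Annotated pseudogenes took 4.75% in Control and 1.67% in Hif1a_siRNA. Gapdh, which has many near-identical pseudogene copies, took 2.21% and 0.211% of reads in the same groups, so the split of reads between such genes and their copies is uncertain.

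**Figure D1:**
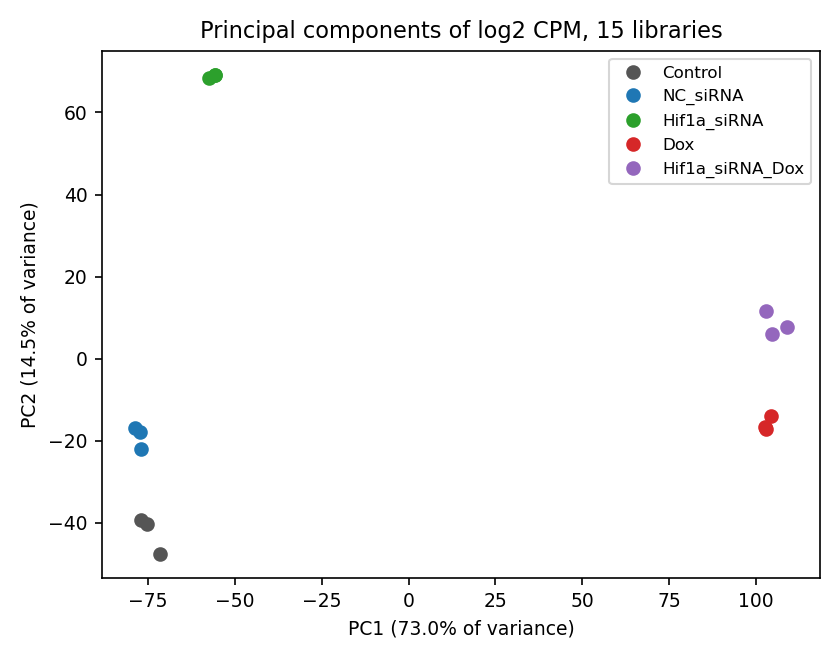
Position of the 15 libraries on the first 2 principal components of log2 CPM, with PC1 (73.0% of variance) on the horizontal axis and PC2 (14.5%) on the vertical axis. Each point is a library coloured by group; the 6 libraries given doxorubicin lie between 102.6 and 109 on PC1, and the other 9 lie below 0.

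Hif1a (gene ID 15251, chromosome 12, 73901324 to 73947554) was low in all 6 libraries given its siRNA. It stood at 217 ± 13 CPM in Control, 274 ± 14 in NC_siRNA, 17.2 ± 1.6 in Hif1a_siRNA, 142 ± 8.9 in Dox and 13.1 ± 1.4 in Hif1a_siRNA_Dox. The siRNA lowered Hif1a 15.9-fold against the negative control siRNA (log2 fold change −3.99 ± 0.09 SE, edgeR adjusted p = 1.2e-20) and by a log2 fold change of −3.44 ± 0.09 in the presence of doxorubicin (edgeR adjusted p = 6.7e-18). Doxorubicin also lowered Hif1a, by −0.61 ± 0.08 without the siRNA and by −0.39 ± 0.09 after it, and these changes did not differ from each other (difference 0.22 ± 0.12, edgeR adjusted p = 0.12). That difference passed the threshold with size factors (RLE) in place of TMM (0.30, edgeR adjusted p = 0.036), with DESeq2 (0.30) and without replicate 2 of Hif1a_siRNA_Dox (0.29, edgeR adjusted p = 0.04). The negative control siRNA raised Hif1a slightly (0.33 ± 0.08).

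**Figure D2:**
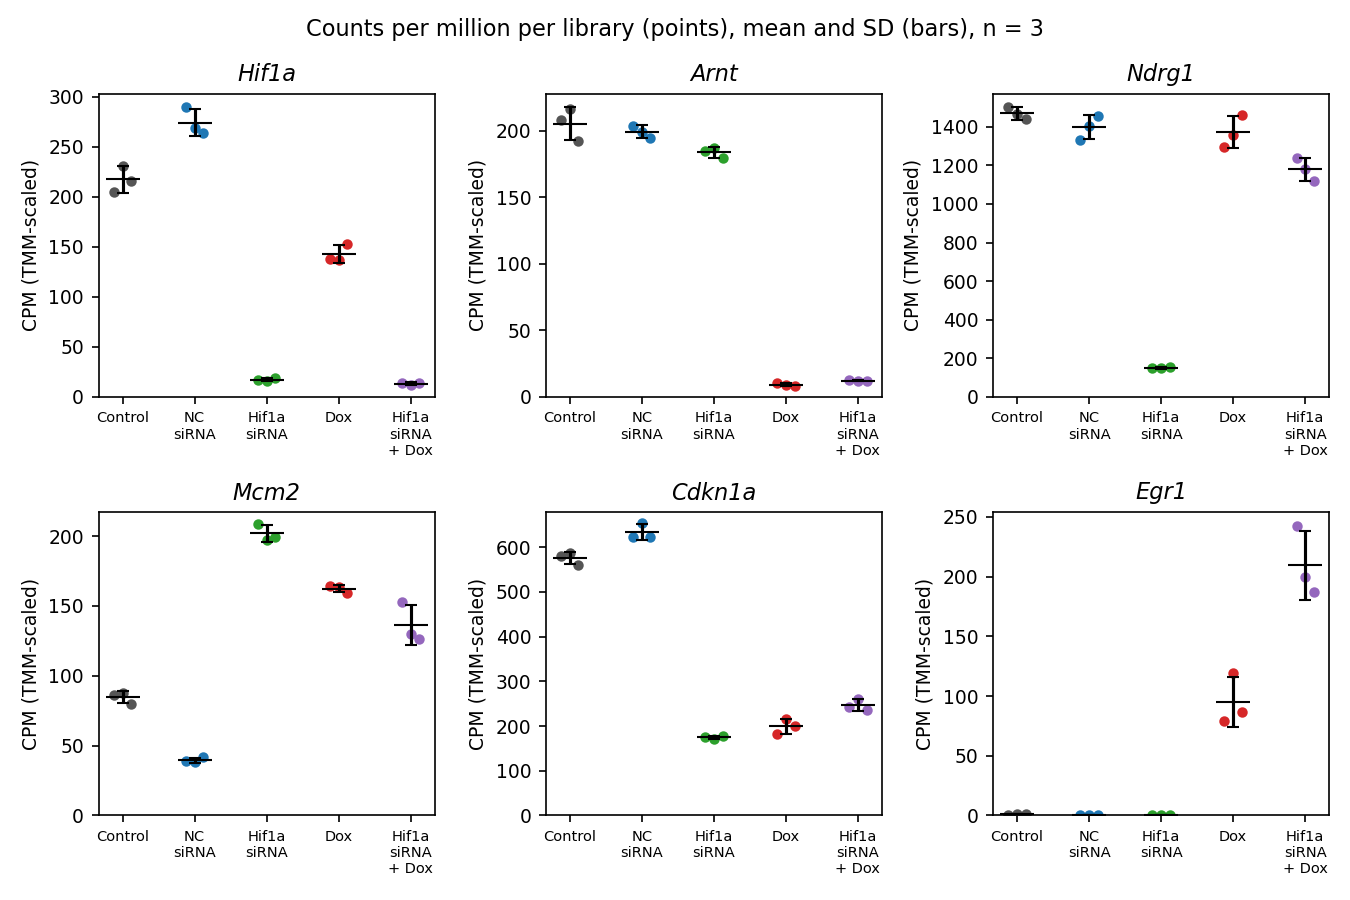
CPM of Hif1a, Arnt, Ndrg1, Mcm2, Cdkn1a and Egr1 in each library (points), with the group mean and SD (bars), n = 3 per group. Hif1a was low in the 6 libraries given its siRNA, Arnt was low in the 6 libraries given doxorubicin, and Ndrg1 was low in Hif1a_siRNA alone (150 ± 2.9 CPM, against 1372 ± 82 in Dox).

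The knockdown comparison, Hif1a siRNA against the negative control siRNA, asked what loss of Hif1a mRNA changed in hypoxic cells. Hypoxia genes fell together. All 26 tested HIF targets outside glycolysis were lower, with a median log2 fold change of −3.05, and 19 of 21 HIF targets in glycolysis were lower, with a median of −2.40. Genes of DNA replication, mitosis and homologous recombination were higher, with medians of 1.73, 1.53 and 1.79.

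Among HIF targets outside glycolysis, Plod2, a collagen lysyl hydroxylase, went from 1503 ± 110 to 108 ± 2.0 CPM (log2 fold change −3.80 ± 0.07, edgeR adjusted p = 1.8e-21). Ndrg1 (chromosome 15, 66929318 to 66969641) went from 1397 ± 63 to 150 ± 2.9 CPM (−3.22 ± 0.07). Bnip3l, a mitophagy receptor, changed by −2.85 ± 0.06 and Fam162a by −3.14 ± 0.07. The list stood apart from other genes (camera adjusted p = 5.45e-17, and adjusted p = 0.000234 with an estimated correlation). All 26 members were lower adjusted over the list alone. In the glycolysis list, Gapdh fell from 13590 ± 570 to 1781 ± 13 CPM (−2.93 ± 0.06), Pdk1, which restrains pyruvate dehydrogenase, from 269 ± 3.4 to 21.6 ± 0.61 CPM (−3.64 ± 0.07), and the lactate exporter Slc16a3 from 325 ± 4.0 to 16.8 ± 1.1 CPM (−4.28 ± 0.09). The glucose transporter Slc2a3 was higher (1.85) and Pfkfb4 did not pass (−0.10). The count lower was again 19 adjusted over the list alone (camera adjusted p = 7.98e-13, and adjusted p = 0.0246 with an estimated correlation). Of 9 HIF subunits and regulators, 6 were lower, a count that holds Hif1a itself, the target of the siRNA. The others include the prolyl hydroxylases Egln1 (−4.03 ± 0.09) and Egln3 (−3.95 ± 0.23) and the HIF antagonist Cited2 (−1.68 ± 0.07). Hif1an was higher (0.64), and Arnt (−0.12) and Egln2 (−0.24) did not pass. The counts were also 6 and 1 adjusted over the list alone (camera adjusted p = 0.000661, and adjusted p = 0.02 with an estimated correlation).

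Of 31 DNA replication genes, 29 were higher, E2f1 was lower (−0.62) and Ccne1 did not pass (0.12). The count higher was also 29 adjusted over the list alone. The helicase subunit Mcm2 (chromosome 6, 88883474 to 88898780) was at 202 ± 6.0 CPM, against 39.6 ± 1.8 with the negative control siRNA and 84.7 ± 4.4 in untreated cells (2.35 ± 0.08, edgeR adjusted p = 8.5e-18). Mcm10 changed by 2.73 ± 0.10 and Uhrf1 by 2.24 ± 0.08. For replication genes camera gave an adjusted p = 1.27e-12, and adjusted p = 0.00866 with an estimated correlation. Of 24 mitosis genes, 23 were higher and Cdc25b was lower (−0.32), with the same counts adjusted over the list alone (camera adjusted p = 2.15e-10, and adjusted p = 0.0374 with an estimated correlation). Levels of mitosis genes in Hif1a_siRNA were above NC_siRNA and lay on either side of Control. Bub1 was at 138 ± 4.3 CPM with the Hif1a siRNA, 31.8 ± 1.8 with the negative control siRNA and 184 ± 8.6 in Control, and Kif11 at 161 ± 1.8, 48.3 ± 2.4 and 85.0 ± 2.6. Of 18 homologous recombination and Fanconi genes, 15 were higher, also 15 adjusted over the list alone, Blm was lower (−0.30) and Xrcc2 and Xrcc3 did not pass (camera adjusted p = 1.7e-06, and adjusted p = 0.00858 with an estimated correlation). Brip1 changed by 3.10 ± 0.14, Bard1 by 2.22 ± 0.12 and Brca1 by 1.73 ± 0.09.

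Of 23 cholesterol synthesis genes, 21 were lower, also 21 adjusted over the list alone, with a median of −0.87, and Dhcr7 and Idi1 did not pass. Nsdhl changed by −1.93 ± 0.08 and Lss by −1.39 ± 0.07. The list's camera adjusted p of 3.74e-07 was lost with an estimated correlation (adjusted p = 0.0994 with an estimated correlation). Of 23 p53 targets, 13 were higher, 4 lower (Cdkn1a, Sesn1, Sesn2 and Ak1) and 6 not passing. There were 13 higher and 6 lower adjusted over the list alone, and the list was not called (camera adjusted p = 0.223). The cell cycle inhibitor Cdkn1a fell from 634 ± 18 to 175 ± 3.6 CPM (−1.86 ± 0.07), and the nuclease gene Aen rose from 12.2 ± 0.82 to 46.4 ± 1.4 CPM (1.92 ± 0.09). The largest increase by the rule for named genes was that of the chemokine Cxcl10 (chromosome 5, 92346638 to 92348889), from 3.87 ± 0.42 to 87.8 ± 2.0 CPM (4.50 ± 0.12, edgeR adjusted p = 3.7e-19), followed by Lrr1, Dctd, Cdca7, Adhfe1 and Steap1 (3.69 to 4.30). The largest decreases were those of Ltbp1 (−6.82 ± 0.36), a TGF-beta binding protein gene near the limit of detection after the siRNA (0.071 ± 0.017 CPM), the costimulatory receptor Tnfrsf9 (−5.86 ± 0.16), Proser2, Gipr, Selenbp1 and Selenbp2. Selenbp1 went from 996 ± 25 to 28.7 ± 1.3 CPM (−5.12 ± 0.08); Selenbp2 is a close copy of it, and the split of reads between them is uncertain.

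In the knockdown comparison, 4636 of 12721 tested genes were higher and 3972 lower, of which 1466 and 1308 by at least 2-fold (edgeR quasi-likelihood test, Benjamini-Hochberg). The size of the excess of higher calls depends on scaling, with 4356 higher and 4233 lower under RLE factors and 4556 and 4043 under upper-quartile factors. The negative control siRNA itself changed many genes, so the direction against NC_siRNA is not always that against untreated cells.

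The doxorubicin comparison, Dox against Control, asked what the drug changed in hypoxic cells whose labels name no siRNA. HIF targets were lower: 22 of 26 outside glycolysis, with a median log2 fold change of −2.40, and 18 of 21 in glycolysis, with a median of −2.11. Arnt, the partner of HIF subunits, fell from 205 ± 12 to 9.19 ± 0.87 CPM. Replication genes were higher (25 of 31, median 1.47), as were all 15 mitochondrially encoded genes and 52 of 79 cytosolic ribosomal protein genes.

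Arnt (gene ID 11863, chromosome 3, 95434367 to 95497240) changed by −4.48 ± 0.08 (edgeR adjusted p = 1.7e-22), Egln1 by −2.51 ± 0.09, Cited2 by −2.35 ± 0.08 and Vhl, whose product marks HIF subunits for degradation, by −2.32 ± 0.10. Of the 9 HIF subunits and regulators 7 were lower, also 7 adjusted over the list alone, and Epas1 (0.97) and Egln3 (1.18) were higher. As a whole the list was not called (camera adjusted p = 0.0673). In glycolysis, the glucose transporter Slc2a1 (chromosome 4, 119108745 to 119137330) fell from 478 ± 44 to 47.9 ± 6.6 CPM (−3.32 ± 0.09), Pfkp by −2.72 ± 0.08, Pdk1 by −2.54 ± 0.07 and Hk1 by −2.21 ± 0.07. Slc2a3 (4.19) and Pfkfb4 (1.07) rose and Pkm did not pass. The count lower was 18 adjusted over the list alone. The glycolysis call was lost with an estimated correlation (camera adjusted p = 2.55e-05, and adjusted p = 0.29 with an estimated correlation). Outside glycolysis, Ero1a, an endoplasmic reticulum oxidase, fell from 5006 ± 820 to 219 ± 4.7 CPM (−4.52 ± 0.10), Bhlhe40 by −4.02 ± 0.08 and Bnip3l by −3.02 ± 0.06. Narf (0.46) and Egln3 rose, Ndrg1 did not pass (1469 ± 34 and 1372 ± 82 CPM), and adjusted over the list alone 22 were lower (camera adjusted p = 1.95e-05, and adjusted p = 0.0233 with an estimated correlation).

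Among replication genes, Fen1 rose from 5.92 ± 0.11 to 65.4 ± 3.1 CPM (3.47 ± 0.09, edgeR adjusted p = 7.4e-20), Lig1 by 2.61 ± 0.08 and Mcm4 by 2.26 ± 0.07. E2f1, Rrm1, Chaf1a and Tipin were lower, and Slbp and Rfc3 did not pass. Of the 31 members 25 were higher adjusted over the list alone (camera adjusted p = 0.000103, and adjusted p = 0.28 with an estimated correlation). The mitochondrial ribosomal RNA mt-Rnr1 changed by 3.45 ± 0.11, mt-Rnr2 by 3.97 ± 0.12, mt-Nd3 by 2.40 ± 0.12 and mt-Co3 by 1.22 ± 0.09. All 15 mitochondrial genes passed adjusted over the list alone (camera adjusted p = 0.00372, and adjusted p = 0.783 with an estimated correlation), beside a mitochondrial share of reads of 3.77% in Dox and 1.43% in Control. Ribosomal protein genes had a median of 0.33, with 6 lower, also 52 higher and 6 lower adjusted over the list alone (camera adjusted p = 0.00867, and adjusted p = 0.783 with an estimated correlation); Rpsa changed by 0.93 ± 0.06 and Rpl12 by 0.87 ± 0.07, and genes matched on genomic span had a median of 0.36. Of 23 p53 targets 14 were higher and 9 lower, with the same counts adjusted over the list alone, and the list was not called (camera adjusted p = 0.473). Plk2 rose by 3.98 ± 0.12 and Aen by 2.78 ± 0.10, while Cdkn1a fell from 576 ± 13 to 199 ± 17 CPM (−1.53 ± 0.07) and the pro-apoptotic Bbc3 from 48.7 ± 4.7 to 8.16 ± 0.93 CPM (−2.57 ± 0.12).

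Among the 12721 genes tested together, Tent5c had the largest increase with doxorubicin by the rule for named genes, from 0.424 ± 0.11 to 154 ± 8.6 CPM (8.49 ± 0.17, edgeR adjusted p = 6.3e-22). The retinoic acid hydroxylase gene Cyp26b1 (7.59 ± 0.19), the immediate early gene Egr1 (6.73 ± 0.22), Oplah, Gpr155 and Tmem79 followed. Genes not listed for all groups are left out of this ranking, among them Mest (6.93 in a fit of Dox and Control). The largest decreases were those of the nuclear long noncoding RNA Neat1, from 726 ± 200 to 6.94 ± 2.2 CPM (−6.71 ± 0.39, edgeR adjusted p = 1.3e-08), the desmosome gene Pkp2 (−6.23 ± 0.11), Angptl6, the clock repressor gene Bhlhe41 (−5.72 ± 0.09) and the linker histone genes H1f0 (−5.71 ± 0.09) and H1f2 (−5.51 ± 0.18). In all, 5586 genes were higher and 5068 lower, 83.8% of 12721, of which 3412 and 3113 by at least 2-fold. Upper-quartile scaling moved the median of all log2 fold changes by 0.126 in this comparison and by 0.149 in that of doxorubicin after the Hif1a siRNA, so changes of that size depend on the scaling.

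**Figure D3:**
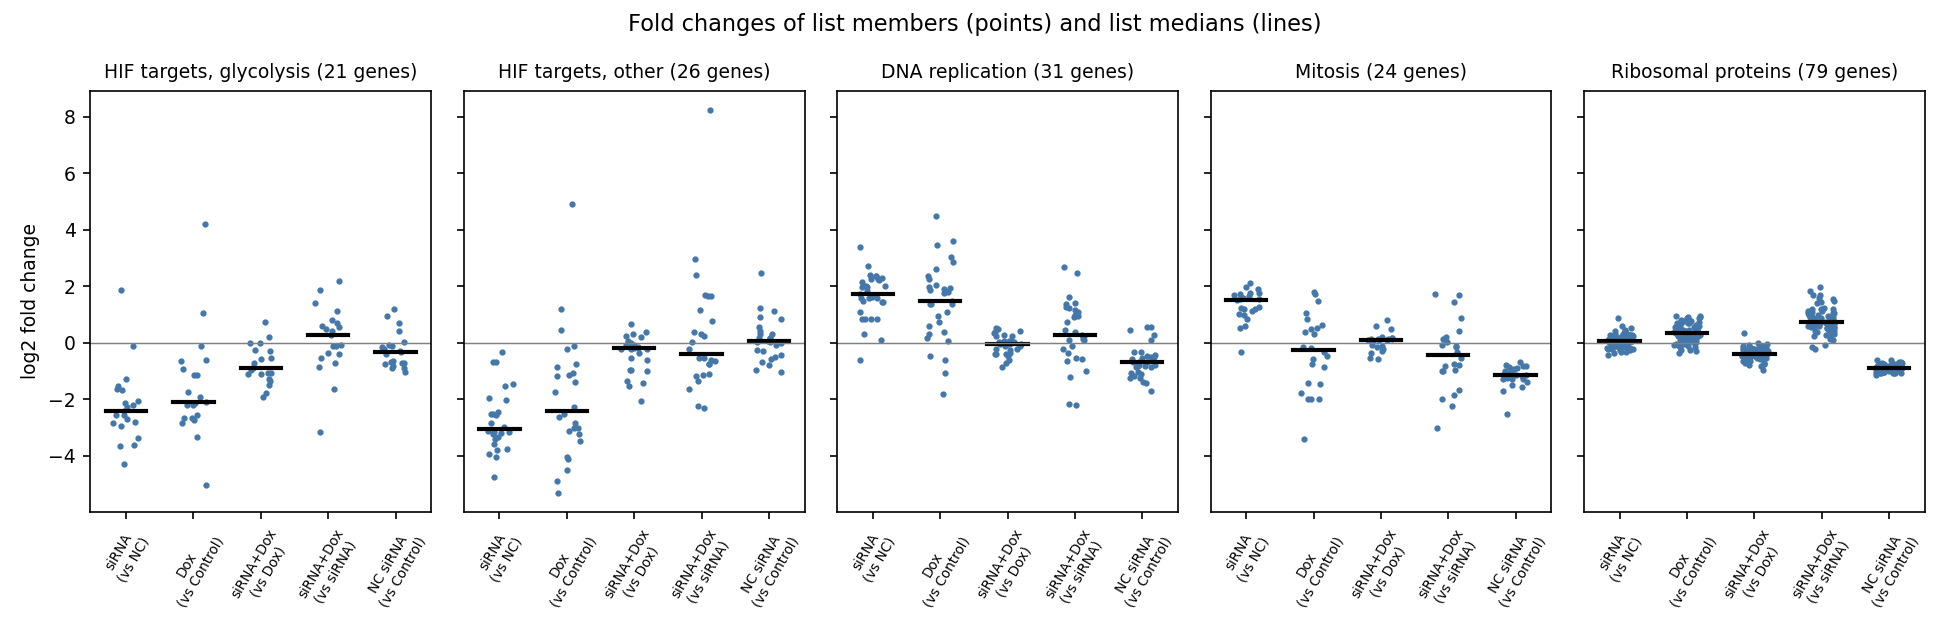
Log2 fold changes of the tested members (points) of 5 gene lists in 5 comparisons, with the median of each as a line: HIF targets in glycolysis (21 genes), HIF targets outside glycolysis (26), DNA replication (31), mitosis (24) and cytosolic ribosomal proteins (79). HIF targets outside glycolysis had medians of −3.05 in the knockdown and −2.40 with doxorubicin, and −0.38 with doxorubicin after the Hif1a siRNA.

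The comparison of doxorubicin after knockdown, Hif1a_siRNA_Dox against Hif1a_siRNA, asked what the drug changed in cells that already had little Hif1a mRNA. HIF targets went both ways: 11 of 26 outside glycolysis were higher and 14 lower, and 11 of 21 in glycolysis were higher and 7 lower. Ribosomal protein genes (71 of 79), all 15 mitochondrially encoded genes and 18 of 23 autophagy and lysosome genes were higher. Arnt fell here too, from 184 ± 4.1 to 12.3 ± 0.12 CPM.

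The HIF lists were not called, with camera adjusted p = 0.809 outside glycolysis, 0.626 in glycolysis and 0.352 for subunits and regulators, and the list outside glycolysis had a median of −0.38 and a mean of 0.25. Adjusted over the list alone, 11 were higher and 14 lower outside glycolysis, 11 and 7 in glycolysis, and 3 and 6 among subunits and regulators. Ndrg1 rose from 150 ± 2.9 to 1179 ± 60 CPM (2.98 ± 0.06, edgeR adjusted p = 3.5e-21), Kdm4b by 1.67 ± 0.08, Pkm by 1.42 ± 0.07 and Slc2a3 by 2.18 ± 0.11. Ero1a fell by 2.25 on the log2 scale and Aldoa by 1.65. Slc2a1 did not pass, at 51.1 ± 1.4 and 47.6 ± 2.3 CPM. Among regulators, Arnt changed by −3.91 ± 0.08, Hif1an by −2.66 ± 0.13 and Vhl by −1.38 ± 0.10, and Epas1, which encodes the HIF-2 subunit, by 1.81 ± 0.12.

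Among ribosomal protein genes, Rplp0 changed by 1.68 ± 0.07 and Rps21 by 1.85 ± 0.08, Rpl3 was lower (−0.21), and adjusted over the list alone 72 were higher (camera adjusted p = 1.88e-08). The list's median was 0.74, and that of genes matched on genomic span 0.57. Mitochondrial genes (median 1.81, 15 adjusted over the list alone, camera adjusted p = 0.00074) stood beside a mitochondrial share of reads of 4.62% against 1.91%. Of the lysosome genes, Ctsl rose by 2.22 ± 0.06, Ctsd by 2.02 ± 0.07 and Hexa by 1.69 ± 0.07; Atg5, Tfeb and Gabarapl1 were lower, and 18 were higher adjusted over the list alone (camera adjusted p = 0.0044). None of these 3 calls held (adjusted p = 0.589 with an estimated correlation, for each list). Targets of the integrated stress response, 14 of 20 lower, did not pass as a list (median −0.87, camera adjusted p = 0.0503), with Cebpg at −4.48 ± 0.10, Trib3 at −4.41 ± 0.10 and the cystine transporter Slc7a11 at −3.69 ± 0.13; 14 were lower adjusted over the list alone. The mitosis list (13 of 24 lower, also adjusted over the list alone) and the homologous recombination list (13 of 18 lower, also adjusted over the list alone) were not called (camera adjusted p = 0.176 for each). Top2a, whose product doxorubicin traps, fell from 575 ± 31 to 71.6 ± 3.8 CPM (−3.01 ± 0.07), whereas the mitotic kinase gene Aurka rose by 1.70 ± 0.07. Of 23 p53 targets 13 were higher and 7 lower, with the same counts adjusted over the list alone (camera adjusted p = 0.424); Btg2 changed by 2.68 ± 0.14 and Bbc3 by −1.80 ± 0.11.

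Egr1 (8.68 ± 0.22), Oplah (7.92 ± 0.16), Fosb (7.89 ± 0.25), Hhatl and the triglyceride synthesis gene Dgat2 (7.02 ± 0.13) had some of the largest increases after the siRNA. Neat1 (−5.81 ± 0.36), H1f0 (−5.39 ± 0.09), Bhlhe41, Arfgef3, Fignl1 and Mtmr3 had the largest decreases. In all, 5423 genes were higher and 5294 lower, 3213 and 3171 by at least 2-fold (edgeR quasi-likelihood test, Benjamini-Hochberg). Of the genes called in both doxorubicin comparisons, which share no library, 8572 (91.1%) changed in the same direction, with 4427 higher in both (2381 for independent lists) and 4145 lower in both (2109), and 840 went in opposite directions (4485). Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.83.

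**Figure D4:**
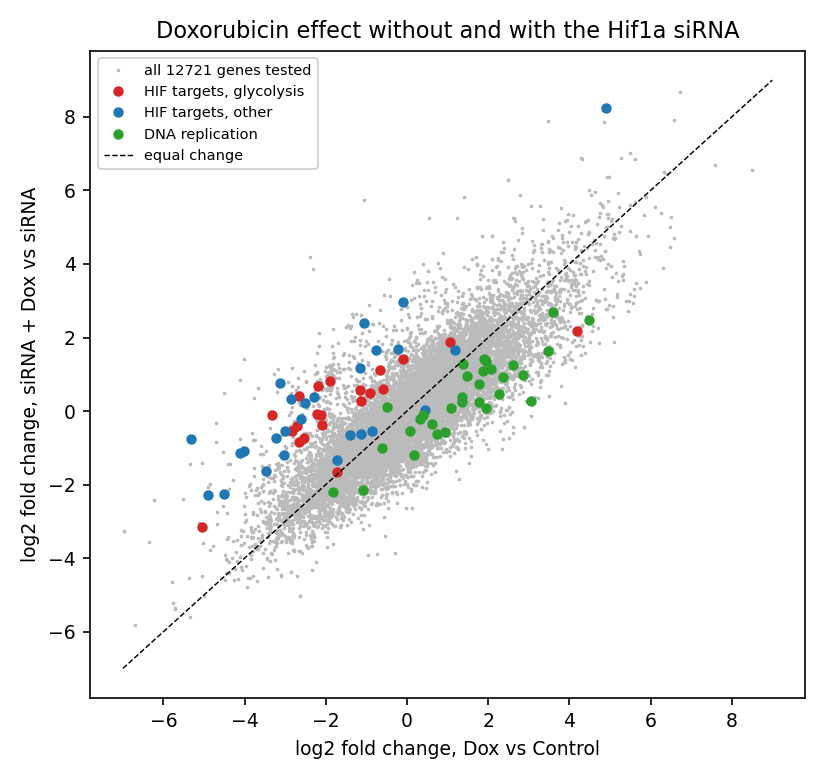
Log2 fold change with doxorubicin without the Hif1a siRNA (horizontal axis) and in cells given the Hif1a siRNA (vertical axis), with a point per tested gene (12721) and HIF target genes marked. Across genes r was 0.83, and most HIF targets lie above the diagonal.

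The difference between these 2 doxorubicin effects was tested as an interaction. HIF targets responded less negatively after the Hif1a siRNA: 24 of 26 outside glycolysis had a higher doxorubicin effect there, with a median log2 difference of 2.45, and 19 of 21 in glycolysis, with a median of 1.81. Ribosomal protein genes (58 of 79, median 0.42) also had a higher effect, and replication genes (29 of 31, median −0.99), homologous recombination genes (15 of 18, median −0.96) and endoplasmic reticulum chaperone genes (14 of 19, median −0.47) a lower one. The labels name no siRNA for Control or Dox and do not say whether Dox cells were transfected. If they were not, any effect of transfection on the response is part of the difference. If they were, the transfection change itself enters the difference with its sign reversed. Ribosomal protein genes fell with transfection (median −0.89). Their siRNA effect had a median of 0.07 against NC_siRNA and −0.38 under doxorubicin against Dox. With NC_siRNA as the reference the direction of their difference may therefore reverse.

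Several HIF targets had similar levels in Hif1a_siRNA, Dox and Hif1a_siRNA_Dox: Slc2a1 was at 51.1 ± 1.4, 47.9 ± 6.6 and 47.6 ± 2.3 CPM, and Egln1 at 29.8 ± 1.7, 36.8 ± 4.4 and 34.8 ± 3.0 CPM. The differences were 3.22 ± 0.12 for Slc2a1 (edgeR adjusted p = 3.3e-16), 2.73 ± 0.12 for Egln1, 2.72 ± 0.08 for Gapdh, 3.07 ± 0.09 for Ndrg1 and 3.17 ± 0.10 for Higd1a. Counts adjusted over the list alone were 24 outside glycolysis (camera adjusted p = 2.39e-15, and adjusted p = 0.000367 with an estimated correlation) and 19 in glycolysis (camera adjusted p = 6.87e-13, and adjusted p = 0.0403 with an estimated correlation), and the members that went the other way were Narf and Slc2a3. Of the 9 regulators 5 had a higher effect, also 5 adjusted over the list alone (Egln1, Cited2, Vhl, Epas1 and Arnt), and Hif1an a lower one (camera adjusted p = 0.012, and adjusted p = 0.0751 with an estimated correlation). Among replication genes Mcm4 differed by −1.80 ± 0.09 and Mcm3 by −1.86 ± 0.11, with 29 lower adjusted over the list alone and E2f1 the other way (camera adjusted p = 1.51e-09, and adjusted p = 0.0364 with an estimated correlation). The Mcm4 level was 32.4 ± 0.31 CPM in Control and 155 ± 7.0 in Dox, and 103 ± 3.9 in Hif1a_siRNA and 143 ± 1.0 in Hif1a_siRNA_Dox.

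For homologous recombination genes (15 lower adjusted over the list alone, Blm higher) camera gave an adjusted p = 0.00316, and adjusted p = 0.058 with an estimated correlation. For chaperone genes (14 lower adjusted over the list alone, Hsp90b1 higher) it gave an adjusted p = 0.00474, and adjusted p = 0.38 with an estimated correlation, with Pdia4 at −1.33 ± 0.12 and Dnajb9 at −1.54 ± 0.14. For ribosomal protein genes (60 higher adjusted over the list alone) it gave an adjusted p = 1.5e-09, and adjusted p = 0.421 with an estimated correlation. Their transcripts are short (median 0.914 kb, against 3.19 kb for all genes), and genes matched on transcript length had a median difference of 0.38, close to the 0.42 of the list. The p53 list was not called (7 higher, 10 lower, and 8 and 11 adjusted over the list alone, camera adjusted p = 0.581), but Cdkn1a fell with doxorubicin without the siRNA and rose after it, from 175 ± 3.6 to 247 ± 13 CPM (difference 2.03 ± 0.09, edgeR adjusted p = 1.3e-14). The largest positive differences were those of Ltbp1, Proser2, Selenbp2, Selenbp1 and Tph1 (4.96 to 6.79) and the largest negative ones those of Cmtr2, Cxcl10, Pprc1, Pigw and Gemin4 (−3.67 to −3.21). Cxcl10 stood at 87.8 ± 2.0 CPM in Hif1a_siRNA and 6.06 ± 0.59 in Hif1a_siRNA_Dox. In all, the effect was higher for 3346 genes and lower for 4109, of which 1171 and 1669 by at least 2-fold. The imbalance over all calls depends on the scaling chosen. RLE factors gave 3769 higher and 3683 lower, while upper-quartile factors kept it, with 3471 higher and 4002 lower.

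The comparison of knockdown under doxorubicin, Hif1a_siRNA_Dox against Dox, asked what the siRNA added to the drug. Changes were smaller: 94 genes were higher and 323 lower by at least 2-fold, against 1466 and 1308 in the knockdown without doxorubicin. Glycolysis genes (17 of 21, median −0.90), ribosomal protein genes (69 of 79, median −0.38) and nuclear genes of oxidative phosphorylation (25 of 30, median −0.41) were lower, and AP-1 and immediate early genes (13 of 16, median 0.61) were higher. The labels name no siRNA for Dox; if those cells were not transfected, effects of transfection are part of this comparison.

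Aldoa went from 4107 ± 210 to 1077 ± 81 CPM (−1.93 ± 0.07, edgeR adjusted p = 9.4e-16), Ldha by −1.78 ± 0.08, Pgk1 by −1.51 ± 0.06 and Eno1 by −1.36 ± 0.07. Hk2 (0.20) and Pfkfb4 (0.75) were higher, and Slc2a1 and Slc16a3 did not pass. Of the 21 members 17 were lower adjusted over the list alone (camera adjusted p = 1.28e-10, and adjusted p = 0.0792 with an estimated correlation). Outside glycolysis 13 of 26 were lower and 4 higher (Bhlhe40, Vegfa, Ero1a and Ddit4), with the same counts adjusted over the list alone (median −0.20, camera adjusted p = 0.0015, and adjusted p = 0.0792 with an estimated correlation); Plod1 changed by −1.53 ± 0.08 and Bnip3l by −1.43 ± 0.06. The subunits and regulators were not called (3 higher and 3 lower, also adjusted over the list alone, camera adjusted p = 0.915), with a median of 0.11 and a mean of −0.35, which Hif1a itself lowers; Arnt rose by 0.41 ± 0.08 from 9.19 ± 0.87 CPM. Ribosomal protein genes were led by Rpl5 (−0.97 ± 0.06) and Rpl3 (−0.71 ± 0.06), with 72 lower adjusted over the list alone (camera adjusted p = 9e-16, and adjusted p = 0.425 with an estimated correlation). Oxidative phosphorylation genes were led by Uqcrc2 (−0.85 ± 0.06) and Atp5f1c (−0.67 ± 0.06), with 27 lower adjusted over the list alone (camera adjusted p = 1.28e-10, and adjusted p = 0.0792 with an estimated correlation). These lists hold short transcripts, and log2 fold changes in this comparison rose with transcript length, by 0.30 ± 0.02 SE per 10-fold.

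Of the AP-1 genes Myc changed by 1.13 ± 0.10, Egr1 by 1.14 ± 0.13, from 94.9 ± 21 to 209 ± 29 CPM, and Ier2 by 1.18 ± 0.14, while Fosb was lower (−0.59). Adjusted over the list alone 14 were higher (camera adjusted p = 4.69e-06, and adjusted p = 0.187 with an estimated correlation). Of 8 NF-kB genes 5 were higher (Ccl5, Nfkb1, Csf1, Relb and Tnfaip3), also 5 adjusted over the list alone, and Nfkbia was lower (camera adjusted p = 0.0361, and adjusted p = 0.162 with an estimated correlation). Of 23 p53 targets 11 were higher, also 11 adjusted over the list alone, and Rrm2b was lower (camera adjusted p = 0.0203, and adjusted p = 0.17 with an estimated correlation); Sesn2 changed by 1.22 ± 0.13 and Bbc3 by 1.10 ± 0.12. The largest increase was that of the chemokine Ccl5, from 1.55 ± 0.42 to 9.84 ± 1.8 CPM (2.66 ± 0.21), followed by Trib1, Zfp473, Ppp1r10, Gsta3 and Klhl18. The largest decrease was that of G6pdx (gene ID 14381, chromosome X, 74409483 to 74428880), which opens the pentose phosphate pathway, from 189 ± 4.5 to 8.61 ± 2.4 CPM (−4.46 ± 0.12, edgeR adjusted p = 3.1e-17). It was also low in Hif1a_siRNA (15.4 ± 0.15 CPM, against 139 ± 3.5 in NC_siRNA). Hif1a, Coro7 (−3.19 ± 0.09), Crtap (−2.98 ± 0.11), Cd302 and Fndc3c1 followed.

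Over all genes, 2733 were higher and 2640 lower (edgeR quasi-likelihood test, Benjamini-Hochberg). The balance depends on scaling, with 3195 higher and 2259 lower under RLE factors and 2377 and 3001 under upper-quartile factors. Of those also called in the knockdown without doxorubicin, 2573 (66.4%) changed in the same direction: 1355 were higher in both (996 for independent lists) and 1218 lower in both (824), and 1303 went in opposite directions (1815). Of the 2573, 1853 were also called in the transfection comparison, in either direction, and 720 were not. Of all tested genes 66.8% were called in transfection, so the count alone says little of a role of transfection. Across genes, which are not independent replicates, the knockdown log2 fold changes without and with doxorubicin had an r of 0.23.

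The combination, Hif1a_siRNA_Dox against Control, set both treatments together against untreated cells. Of the HIF targets in glycolysis 19 of 21 were lower, with a median of −2.90, and of those outside glycolysis 23 of 26, with a median of −2.48. Replication genes (24 of 31, median 1.53), mitochondrially encoded genes (13 of 15, median 1.83) and interferon-stimulated genes (16 of 22, median 1.76) were higher.

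Ldha went from 6646 ± 440 to 449 ± 55 CPM (−3.89 ± 0.08, edgeR adjusted p = 1.5e-21), Aldoa by −3.66 ± 0.07, Pdk1 by −3.66 ± 0.08 and Gapdh by −3.01 ± 0.06, while Slc2a3 and Pfkfb4 rose. In this list 19 were lower adjusted over the list alone (camera adjusted p = 1.35e-06, and adjusted p = 0.178 with an estimated correlation). Outside glycolysis Bnip3l changed by −4.45 ± 0.06 and Higd1a by −3.81 ± 0.07, while Narf rose. Of the 26 members 23 were lower adjusted over the list alone (camera adjusted p = 1.35e-06, and adjusted p = 0.0138 with an estimated correlation). Of 9 subunits and regulators 6 were lower, also 6 adjusted over the list alone, with Arnt at −4.07 ± 0.08, and Epas1 was higher (camera adjusted p = 0.0469, and adjusted p = 0.178 with an estimated correlation). Hif1a, the target of the siRNA, is among those lower and counts toward this call. Rrm2 rose by 2.76 ± 0.09 among the replication genes, of which E2f1, Rrm1, Chaf1a and Tipin were lower (24 higher adjusted over the list alone, camera adjusted p = 0.000183, and adjusted p = 0.178 with an estimated correlation). The mitochondrial list (13 adjusted over the list alone) had a camera adjusted p = 0.00175, and adjusted p = 0.589 with an estimated correlation, beside shares of reads of 4.62% and 1.43%. Of the interferon-stimulated genes Parp14 rose from 1.04 ± 0.42 to 57.1 ± 2.7 CPM (5.77 ± 0.19) and Isg15 from 1.39 ± 0.47 to 22.7 ± 1.9 CPM (4.03 ± 0.19), while Isg20 was lower. The count higher was 16 adjusted over the list alone (camera adjusted p = 0.0268, and adjusted p = 0.433 with an estimated correlation). Of 23 p53 targets 14 were higher and 7 lower, with the same counts adjusted over the list alone, and the list was not called (camera adjusted p = 0.178); Plk2 changed by 4.51 ± 0.13. Among the genes tested together, the largest increases by the rule for named genes were those of Tent5c (8.47 ± 0.17), Cyp26b1, Egr1, Zfp791, Rhpn2 and Oplah. The largest decreases there were those of the carbonic anhydrase gene Car9, from 235 ± 12 to 1.88 ± 0.77 CPM (−6.96 ± 0.17), Pkp2, Neat1, H2ac25, Kctd16 and Eno2. H2ac25 varied between Control libraries (14.1 ± 9.9 CPM). In all, 5525 genes were higher and 5246 lower, 3436 and 3209 by at least 2-fold.

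The transfection comparison, NC_siRNA against Control, measured what lipoplexes with a control siRNA changed. All 79 ribosomal protein genes (median −0.89), all 24 mitosis genes (median −1.12) and all 30 nuclear oxidative phosphorylation genes (median −0.67) were lower. Cholesterol synthesis genes were higher (14 of 23, median 0.35). Of 9 HIF subunits and regulators 7 were higher (median 0.38), while 13 of 21 glycolysis genes were lower (median −0.31).

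Rpl8 changed by −1.05 ± 0.06, Rps2 by −1.14 ± 0.06 (edgeR adjusted p = 1e-12) and the ATP synthase gene Atp5f1b by −1.26 ± 0.07; ribosomal protein genes took 4.58% of reads, against 7.22% in Control. Log2 fold changes in this comparison rose with transcript length, by 1.20 ± 0.03 SE per 10-fold, and the median transcript length was 0.914 kb for ribosomal protein genes, 1.30 kb for oxidative phosphorylation genes, 3.28 kb for mitosis genes and 3.19 kb for all genes. Bub1 fell from 184 ± 8.6 to 31.8 ± 1.8 CPM (−2.53 ± 0.07, edgeR adjusted p = 2.6e-17), Nusap1 by −1.57 ± 0.08 and the proliferation marker Mki67 from 450 ± 5.8 to 172 ± 6.7 CPM (−1.39 ± 0.06). The counts were also 79, 24 and 30 adjusted over the list alone. None of the 3 calls held with an estimated correlation: for ribosomal proteins camera adjusted p = 9.71e-23 and adjusted p = 0.21 with an estimated correlation, for mitosis 1.08e-12 and adjusted p = 0.0669 with an estimated correlation, and for oxidative phosphorylation 3.47e-10 and adjusted p = 0.0669 with an estimated correlation.

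Hmgcs1 rose from 76.3 ± 8.8 to 303 ± 41 CPM (1.99 ± 0.11) and Insig1 by 1.04 ± 0.10, while Lss, Mvk, Pmvk, Fdps and Mvd fell. Adjusted over the list alone 14 were higher (camera adjusted p = 0.0329, and adjusted p = 0.481 with an estimated correlation). Egln3 rose by 2.48 ± 0.21 and Egln1 by 1.22 ± 0.08 (7 regulators adjusted over the list alone, camera adjusted p = 0.0183, and adjusted p = 0.0902 with an estimated correlation). In glycolysis Gapdh fell by 0.90 on the log2 scale and Eno1 by 0.90, while Slc16a3 (1.19 ± 0.08), Hk2 (0.94 ± 0.07), Pdk1 and Slc2a1 rose. Adjusted over the list alone 14 were lower (camera adjusted p = 0.0329, and adjusted p = 0.481 with an estimated correlation). HIF targets outside glycolysis (11 higher, 9 lower, the same adjusted over the list alone, camera adjusted p = 0.82), p53 targets (8 higher, 5 lower, and 8 and 4 adjusted over the list alone, camera adjusted p = 0.321) and mitochondrially encoded genes (8 higher, 2 lower, the same adjusted over the list alone, camera adjusted p = 0.11) were not called. Rasl11b (3.38 ± 0.20), Gcnt2, Prss23, Gbp2, Fbxo32 and Nr4a2 had the largest increases. The heat shock genes Hspa1a (−3.07 ± 0.25) and Hspa1b (−3.06 ± 0.26), which are close copies with reads that cannot be assigned with certainty, Ano3, Tinagl1, Fam149a and Aven had the largest decreases. In all, 4211 genes were higher and 4291 lower, 1123 and 887 by at least 2-fold (edgeR quasi-likelihood test, Benjamini-Hochberg).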

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

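Among the tests in this part, those of the detection floor, of transfection alone, of scaling, of a few genes taking most of the counts and of transcript length or genomic span within single gene lists were chosen only after the result was seen, as was the fit of genes listed in both groups.

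The doxorubicin effect differed between cells with and without the Hif1a siRNA by a test of the difference itself. It was higher after the siRNA for 3346 genes and lower for 4109. Splits of the 12 libraries into 4 groups of 3 were drawn at random, 100 with the real one included. The real split alone (1 of 100) gave as many genes (7455, highest other 5211) and as many lists (14, highest other 12, again 1 of 100). Mixed groups hold libraries with different treatments, which widens the spread within groups whether or not the doxorubicin effects differ. The splits therefore cannot exclude chance for the difference itself. The median of the other splits was still 6 lists, so the list count says little of any single list. Camera may call lists from the part of the real difference that mixed groups keep, which was not tested. The 14 lists had median log2 differences of 0.58 for HIF subunits and regulators, 1.81 for HIF targets in glycolysis, 2.45 for HIF targets outside glycolysis, 0.42 for cytosolic ribosomal proteins, 0.37 for oxidative phosphorylation, 0.45 for cholesterol synthesis, 0.28 for autophagy and lysosome, 0.95 for AP-1 genes, 1.04 for replication-dependent histones and 0.43 for invasion genes. The medians were −0.99 for DNA replication, −0.96 for homologous recombination, −0.71 for interferon-stimulated genes and −0.47 for endoplasmic reticulum chaperones. Of these 14 calls only 3 held with an estimated correlation, those of both HIF target lists and of DNA replication.

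Single genes that differed in the same test included Ltbp1 (6.79), Proser2 (6.16), Selenbp2 (5.43), Selenbp1 (5.01) and Tph1 (4.96) at the top, and Cmtr2 (−3.67), Cxcl10 (−3.55), Pprc1 (−3.38), Pigw (−3.25) and Gemin4 (−3.21) at the bottom. Among HIF regulators the differences were 2.73 for Egln1, 1.66 for Cited2, 0.94 for Vhl and 0.58 for Arnt. Among HIF targets they were 2.72 for Gapdh, 3.22 for Slc2a1, 2.89 for Aldoc, 3.09 for Slc16a3, 3.07 for Ndrg1, 3.17 for Higd1a, 2.68 for Fam162a and 2.93 for Bhlhe40. Among p53 targets they were 2.03 for Cdkn1a, 1.04 for Bax, −2.08 for Aen and −2.09 for Rrm2b. Ribosomal protein genes differed by 0.84 (Rpl13a), 0.87 (Rps4x), 0.85 (Rplp0) and 0.77 (Rpl9), and replication genes by −1.80 (Mcm4), −1.86 (Mcm3) and −1.83 (Fen1). Repair genes differed by 1.14 (Blm), −1.71 (Bard1), −1.69 (Brip1) and −1.30 (Rad51ap1), and chaperone genes by −1.13 (Pdia3), −1.33 (Pdia4), −1.54 (Dnajb9) and −1.08 (Hyou1).

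Genes outside the 12721 were tested in fits of 2 groups. Of the 359 such genes with doxorubicin, 296 were higher and 1 lower, among them the imprinted gene Mest (6.93) and the hedgehog target Gli1 (5.89). For doxorubicin after knockdown 77 of 122 were higher and 8 lower, for the combination 261 and 6 of 352, for transfection 24 and 1 of 98, for knockdown under doxorubicin 24 and 15 of 302, and for the knockdown 3 and 4 of 44. A gene low in Control is listed for Dox only if its reads in Dox are high enough, so the listing itself favours increases over Control.

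HIF targets outside glycolysis fell with doxorubicin without the Hif1a siRNA and not, as a list, after it. Counts at the detection floor after the siRNA are excluded as the cause, since 88.5% of the members (23 of 26) had a mean of at least 100 reads per library there. Transfection by itself did not lower the list: NC_siRNA against Control had a median of 0.05, with 11 members higher and 9 lower. This argues against transfection alone as the cause. With NC_siRNA as the reference the median difference was 2.48, above 0 for 26 of 26 members. That value is the tested difference plus the transfection change, so it is no separate evidence. An interaction of transfection with doxorubicin stays open because no group had the control siRNA with the drug. A biological hypothesis is that doxorubicin lowered Hif1a-dependent transcription: 1263 genes at least 2-fold lower with the siRNA and in no HIF list had a median doxorubicin change of −0.57, which was −0.60 from that of expression-matched genes, consistent with it, although 413 of them rose. After the siRNA they had a median change of 0.82, which was 0.81 above matched genes, with 759 higher and 305 lower. The hypothesis alone does not predict this rise, but that comparison has as its reference the libraries by which the genes were chosen as low. The 1263 genes were also chosen against NC_siRNA alone. Genes that the control siRNA itself raised can be among them, and 1123 tested genes rose at least 2-fold with it. How many of these are in the set was not counted, so the set does not decide the hypothesis.

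Doxorubicin changed 83.8% of the genes. Scaling of the libraries is excluded as the cause, since 51.5% of genes lay over 1 log2 from the median change. So are a few genes taking most of the counts. The 10 most counted genes held 11.7% of reads in Control and 11.89% in Dox, a difference of 0.19 percentage points. That test does not cover broader shifts in composition, such as ribosomal protein genes at 7.22% of reads in Control and 9.81% in Dox. Transcript length is excluded as a common cause because its slopes had opposite signs, 0.50 ± 0.07 SE per 10-fold without and −0.38 ± 0.07 after the siRNA. Genomic span remains: the change fell by 0.54 ± 0.04 SE per 10-fold of span (slope −0.54) without and by 0.48 ± 0.03 after the siRNA, against slopes of 0.03 ± 0.02 in the knockdown, −0.06 ± 0.01 in the knockdown under doxorubicin and −0.15 ± 0.01 with transfection. A weaker slope of the same sign thus also arose without the drug. A candidate explanation is that the drug hampers transcription through long genes, but span may account for only part of the changes. The median change was 0.38 in the 1104 genes of shortest span and −0.27 in the 1104 of longest without the siRNA, and 0.64 and −0.36 after it.

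The negative control siRNA lowered ribosomal protein, oxidative phosphorylation and mitosis genes, in a comparison where changes rose with transcript length. For ribosomal protein genes the median lay −0.42 from that of length-matched genes and below the lowest matched median (−0.88 against −0.67), and for mitosis genes −1.20, so transcript length is excluded as the whole cause for both. For oxidative phosphorylation genes the distance was −0.27, within the range of matched genes, and length and a response to transfection cannot be told apart. Histone genes (14 of 21 lower) lay −0.59 from length-matched genes and below their lowest median (−1.04 against −0.96), so length is excluded as the whole cause there too. Histones took only 0.016% of reads in Control and 0.01% in NC_siRNA, in libraries made with an mRNA kit, so their shift rests on few reads. A biological explanation, slower growth after transfection, was not tested.

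The doxorubicin effect was higher after the siRNA for 58 of 79 ribosomal protein, 17 of 30 oxidative phosphorylation (2 were lower) and 10 of 21 histone genes, lists of short transcripts. These directions have Control, not NC_siRNA, as the reference. The siRNA effect against NC_siRNA had medians of 0.07, 0 and 0.01 in these lists. Under doxorubicin, against Dox, the medians were −0.38, −0.41 and 0.31. With NC_siRNA as the reference the first 2 directions may therefore reverse. The calls were lost with an estimated correlation (adjusted p = 0.421, adjusted p = 0.38 and adjusted p = 0.126 with an estimated correlation), and the difference changed with transcript length (slope −0.88 ± 0.04 SE per 10-fold). For ribosomal protein genes the median lay 0.04 from that of length-matched genes and for oxidative phosphorylation genes 0.09, so length, or what goes with it, may account for both. For the median of all 21 histones the distance was 0.70, above the highest matched median (1.04 against 0.89), so length is excluded as the whole cause. Histones took at most 0.016% of reads in any group mean, so this too rests on few reads. Within each doxorubicin comparison ribosomal protein genes, of short genomic span (median 3.17 kb, against 24.4 kb for all genes), lay −0.03 from span-matched genes without the siRNA and 0.17 after it, so span may account for their increase. From length-matched genes they lay 0.15 without the siRNA and 0.22 after it. Since the slope on transcript length at a given span was positive without the siRNA, the match there does not point to length, and the role of length stays open in both.

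Splits of the libraries into groups of 3 are 10 per comparison with the real one included, too few for a share under 0.05. The real split alone (1 of 10) gave as many genes in each of the 6 comparisons: 8608 in the knockdown, 10654 with doxorubicin, 5373 in the knockdown under doxorubicin, 10717 with doxorubicin after knockdown, 8502 with transfection and 10771 in the combination. The highest other split gave 1 gene in the knockdown under doxorubicin and 0 in the other 5. For gene lists, the splits that gave at least as many as the real one, with the real one counted, were 5 in the knockdown (12, highest other 13), 6 with doxorubicin (5 and 7), 3 in the knockdown under doxorubicin (8 and 10), 7 with doxorubicin after knockdown (5 and 8), 2 with transfection (12 and 12) and 3 in the combination (6 and 6). Splits that mix the groups keep part of the real difference, and camera with a preset correlation may call lists from it, which was not tested. Fewer lists were called with an estimated correlation in each comparison, so the list calls rest on the correlation assumed.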

How the results depend on the processing

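The fits of genes listed in both groups and of protein-coding nuclear genes only were chosen after seeing the data. Of 360 values for 25 counts under other settings, 344 were within 1.5 times the reported count. The other 16 were as follows. With an adjusted p under 0.01 the knockdown overlap was 1699 genes in the same direction and 771 in opposite directions. Gene lists called by camera with an estimated correlation and by fry were 7 and 21 in the knockdown, 1 and 22 with doxorubicin, 0 and 21 in the knockdown under doxorubicin, 0 and 24 with doxorubicin after knockdown, 0 and 22 with transfection, 1 and 23 in the combination, and 3 and 22 in the difference. Camera with an estimated correlation allows for genes of a list moving together, and fry does not compare a list with other genes.

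Named genes were mostly chosen for large changes or small adjusted p, so their stability says little of other called genes. Of 5156 values for named genes, 5153 kept their direction and their side of the threshold and 0 reversed. The other 3 concern Hif1a in the difference of the doxorubicin effects, over the threshold with size factors (RLE) (0.30, edgeR adjusted p = 0.036), DESeq2 (0.30, DESeq2 adjusted p = 0.033) and without Hif1a_siRNA_Dox replicate 2 (0.29, edgeR adjusted p = 0.04), with adjusted p from 0.033 to 0.32 over all alternatives. The cause was not tested.

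Leaving out each library in turn gave 4311 to 4418 genes higher and 3721 to 3767 lower in the knockdown, 2231 to 2709 and 2126 to 2738 in the knockdown under doxorubicin, and 5456 to 5536 and 4953 to 5005 with doxorubicin. It gave 5099 to 5379 and 5217 to 5401 with doxorubicin after knockdown, 3949 to 4045 and 3869 to 4083 with transfection, 5324 to 5460 and 5142 to 5344 in the combination, and 3033 to 3362 and 3945 to 4263 in the difference. Upper-quartile factors moved the median of all genes by over 0.1 with doxorubicin and with doxorubicin after knockdown, and the fit of genes listed in both groups moved it by −0.106 with doxorubicin. The filter removed 0 genes, so the fit without it tests nothing. Replicate numbers do not pair the libraries: over 30 pairs of libraries with the same number in different groups 0 correlated above 0.1, and a replicate block gave 4605 genes higher and 3935 lower in the knockdown.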

Other observations

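Lists not described so far also moved. In the knockdown 15 of 20 integrated stress response genes were higher (median 1.21, camera adjusted p = 0.000199, and adjusted p = 0.178 with an estimated correlation), while 15 of 23 autophagy and lysosome genes (median −0.44, camera adjusted p = 0.00435, and adjusted p = 0.357 with an estimated correlation) and 9 of 12 angiogenic factors (median −0.84, camera adjusted p = 0.0421, and adjusted p = 0.269 with an estimated correlation) were lower. Invasion and mesenchymal genes were lower too, 11 of 16 (median −1.02, camera adjusted p = 0.012, and adjusted p = 0.0478 with an estimated correlation). Melanocyte and pigmentation genes were higher in the knockdown (10 of 17, median 0.56, camera adjusted p = 0.0428) and lower in the knockdown under doxorubicin (11 of 17, median −0.36, camera adjusted p = 0.00611) and with transfection (11 of 17, median −0.79, camera adjusted p = 0.00429). With doxorubicin after knockdown 9 of 11 MHC class I genes (median 2.01, camera adjusted p = 0.0117) and 11 of 12 angiogenic factors (median 1.48, camera adjusted p = 0.00465) were higher. With transfection replication genes (26 of 31, median −0.70, camera adjusted p = 2.44e-06), repair genes of homologous recombination (12 of 18, median −0.61, camera adjusted p = 0.00133), stress response genes (15 of 20, median −0.72, camera adjusted p = 0.00133), replication-dependent histones (14 of 21, median −1.04, against −0.45 for genes matched on transcript length, camera adjusted p = 0.0115) and NRF2 targets (11 of 20, median −0.25, camera adjusted p = 0.0329) were lower. Other than invasion genes, none of the lists in this paragraph was called with an estimated correlation. Histone reads are shared between near-identical genes.

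Apoptosis genes (11 of 19 higher and 7 lower with doxorubicin, median 0.47, camera adjusted p = 0.651) and genes of doxorubicin transport and metabolism (8 of 15 higher and 6 lower, median 0.29, camera adjusted p = 0.968) were not called in any of the 7 comparisons. Marker lists had too few tested members for a test. Of 16 immune cell markers 1 was tested, Cd68, at 23.4 ± 5.9 CPM in Control and 4.92 ± 1.1 in Dox. Of 16 fibroblast and endothelial markers 4 were tested: Col1a1 was at 5.49 ± 0.16 CPM in Control, 46.7 ± 12 in Dox and 61.4 ± 12 in Hif1a_siRNA_Dox, Pdgfra at 0.963 ± 0.14, 3.81 ± 0.33 and 8.83 ± 1.9, Pdgfrb at 14.4 ± 0.82, 18.3 ± 1.5 and 25.3 ± 1.7, and Postn at 9.36 ± 0.31, 18.9 ± 0.74 and 11.9 ± 0.56.

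Off-target silencing by seed matches of the siRNA in 3' UTRs was tested without the siRNA sequence, which was not used here. Of 4178 7-mers of the Hif1a mRNA, the carriers of ATCCCAA (947 genes) were lowest in the knockdown (shift −0.15). In the knockdown under doxorubicin their shift was −0.04, and 4.71% of all 7-mers had carriers as low. The same carriers were also lower with transfection (shift −0.07) and in Dox against Control (shift −0.12), where the labels name no Hif1a siRNA. Such matches may contribute, and the test does not decide it.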
